A study of Populus ussuriensis with 20 samples.

How the data were processed

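RNA was taken from the basal 0.5 cm of in vitro stem cuttings of Populus ussuriensis, a poplar. Wild-type plants (WT) and plants carrying PuHox52 behind the cauliflower mosaic virus 35S promoter (OE) were sampled at 6, 12, 24, 48 and 96 h after cutting. Per the labels, each of the 10 groups held 2 biological replicates of 40 cuttings each, and sequencing used 125-bp paired-end reads. The series text gives an age of 2 weeks for the plants and the growth protocol 4 weeks. Growth conditions were given as 16 h of light and 8 h of dark. The labels carry no replicate numbers, so the replicate numbers used here only name libraries within a group and pair nothing across groups. The labels do not say how many transgenic lines the OE cuttings came from.

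Per the file headers, each library had 1 table of the same 39538 gene models with a count, an FPKM value and a normalized value for each. TopHat2 2.1.1 and HTSeq 0.6.0 are named in the submitters' processing notes, which give neither their role nor their order. The genome build, the annotation release and the strand setting are not given in the sources used here, and coordinates are those of the deposited tables. Most gene IDs end in .v3.0, and 261 gene models carry names with newGene. The deposited count column held whole numbers whose totals differed between libraries, and the tests were run on it. The deposited normalized values were treated as a signal scaled by the authors with 1 factor per library. Divided by that factor, they equalled the count (tolerance 0.05 plus a relative 0.001) in 76.9 to 81.96% of gene models per library. The count was higher by up to 1 in up to 23.1%. These shares include gene models with 0 counts, which equal trivially, as only 28168 to 29980 models per library had counts. Among models with counts, the share that was higher is therefore larger. A deposited count may therefore have been rounded up, and a count of 1 can stand for a value close to 0. The deposited FPKM and signal columns were described but not tested. No table entry lacked a gene ID.

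Total counts ranged from 10399262 to 27472303 per library. Of the gene models, 6602 had 0 counts in all 20 libraries, and 26391 were tested after edgeR's filterByExpr with its default settings. These held at least 99.94% of the counts of each library.

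Tests used R 4.3.3 with edgeR 4.0.16. Library sizes were scaled by the trimmed mean of M values (TMM), and 1 group-means model was fitted over all 20 libraries, which left 10 residual degrees of freedom per gene. The quasi-likelihood test (glmQLFit and glmQLFTest) was followed by Benjamini-Hochberg adjustment over all genes tested in a comparison, and a gene is said to be called when its adjusted p was under 0.05. The comparisons were OE against WT averaged over the 5 times, OE against WT at each time, a test of whether the OE minus WT difference changed over the times, and each later time against 6 h within each genotype. Standard errors (SE) of log2 fold changes were the size of the change divided by the square root of the F statistic. Levels are given as CPM, counts brought to a common library size after TMM scaling, as mean ± SD of 2 libraries. The biological coefficient of variation over all genes was 0.115. Replicate pairs differed by more than sampling noise in every group (chi-square per degree of freedom 4.64 to 17), and their Spearman correlations across genes were 0.9877 to 0.9931.

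Named genes followed a rule fixed before the data were examined. For each comparison they were the largest changes in each direction among called genes with a mean log2 CPM of at least 1. In the average, the sign had to be the same at all 5 times. At single times, both libraries of a group had to lie on the same side of both libraries of the other group. For the change of the genotype difference over time, the smallest adjusted p decided. Only 2 IDs per direction are named, and of the comparisons with 6 h only the genes at 96 h, because the files used here do not pair IDs with gene names or products. For the same reason the gene lists by product, the homeodomain-leucine zipper family to which PuHox52 belongs, the homologues of the study's regulators and the markers of stem cell types could not be formed, and no gene set test was run. No ID could be tied to PuHox52, so its level was not used to check the labels. Where a group had 0 counts, the fold is a lower bound against a floor of 3 counts over the group. With 1 to 3 counts, the ratio of counts scaled by library size is given with its 95% counting interval. Such floors and intervals cover counting error only.

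The edgeR test was tested on simulated counts, with 200 genes changed. These counts were drawn from the libraries' means and sizes and edgeR's own estimate of each gene's spread, so its model held by construction. For the average over times edgeR recovered 79.1%, 88.1% and 97% of genes changed by 1.5, 2 and 4-fold (53, 59 and 64 genes). It made 13 false calls among 26178 genes. For OE against WT at 6 h it recovered 28.4%, 59.7% and 81.8% (19, 40 and 54 genes), with 9 false calls. On the same counts DESeq2 recovered 79.1%, 86.6% and 98.5% in the average with 27 false calls, and 40.3%, 61.2% and 83.3% at 6 h with 17. For the change over time, where no simulated difference varied between times, DESeq2 made 25 false calls and edgeR 0.

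A scan for neighbouring genes that differed together was added after the data had been explored. It used the OE minus WT difference in log2 CPM, averaged over times and limited to 1 in size, of 19143 genes with a mean log2 CPM of at least 2, in order along the chromosomes. It looked for runs of 5 to 300 genes scoring above the highest score in 100 shuffles of gene order. On simulated runs it found 20 of 20 runs of 14 genes shifted by -0.5, 20 of 20 runs of 150 genes shifted by 0.2, and 13 of 20 shifted by 0.1. Python 3.11.15 with numpy 2.4.6 was used for the scan.

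The alternatives chosen before the data were examined were DESeq2 1.42.0 (Wald test, and a likelihood ratio test for the change over time), edgeR with median-of-ratios size factors, no filter, a filter of CPM of at least 1 in at least 4 libraries, robust empirical Bayes, an additive model, a test against a log2 fold change of 1 (glmTreat), fits on the 4 libraries of a time or the 10 of a genotype, and leaving out each library in turn. A group left with 1 library was assumed to vary like the others. Leaving out the genes of the segments, thinning all libraries to the smallest total, and lowering each count by 1 were chosen after seeing the data.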

Results

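The basal ends of WT and OE stem cuttings were profiled by RNA sequencing at 6, 12, 24, 48 and 96 h after cutting, over the period in which adventitious roots form. Each of the 10 groups had 2 libraries. The libraries held 10399262 to 27472303 counts each, with counts at 28168 to 29980 gene models per library. The 10 most abundant genes took 2.18 to 8.81% of the counts of a library, with the highest shares in the WT libraries at 96 h. The first principal component of log2 CPM (50.9% of the variance) ordered the times from 6 h to 96 h, and the second carried 12.1%. On the third (7.53%) the genotypes lay apart at each time, with OE lower at 6 and 48 h and higher at 12, 24 and 96 h. At 24 h the WT libraries stood at -15.26 and -15.57 and the OE libraries at 13.68 and 22.11.

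**Figure D1:**
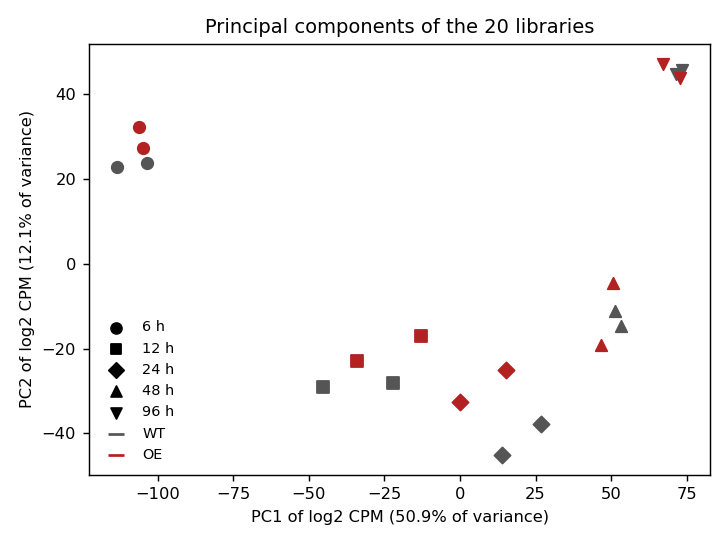
First and second principal components of log2 CPM for the 20 libraries, with 1 point per library, time shown by the symbol and genotype by colour (WT grey, OE red). The first component, 50.9% of the variance, runs from the 6 h libraries on the left to the 96 h libraries on the right in both genotypes.

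The first question was how transcripts at the stem base changed after cutting in each genotype. None of the 10 groups was uncut, and the labels give times since cutting only. Differences from 6 h can therefore combine time since cutting with time of day under the light cycle. In WT, Potri.013G011700.v3.0 (chromosome 13, 748665 to 749582) had 0 counts at 6 h and 886 at 96 h over both libraries, at least 205-fold higher (27.4 ± 16.6 CPM at 96 h, n = 2). Potri.005G182700.v3.0 went from 0 to 172 counts, at least 39.7-fold higher. In the opposite direction, Potri.001G099000.v3.0 went from 143 counts at 6 h to 0 at 96 h, at least 68.8-fold lower. Potri.004G037900.v3.0 went from 237 counts to 1, a ratio of 342 (95% counting interval 60.8 to 13600). The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment gave adjusted p of 9.5e-06, 1.01e-06, 8.22e-08 and 1.31e-07 for these 4 genes. It called 4632 genes higher and 4860 lower in WT at 12 h than at 6 h, 6361 and 6684 at 24 h, 7515 and 7207 at 48 h, and 7974 and 7962 at 96 h. The count at 12 h, 9492, was 6059 without WT 6 h replicate 2 and 5841 without WT 12 h replicate 2.

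In OE, Potri.013G011700.v3.0 again went from 0 counts at 6 h to 765 at 96 h, at least 165-fold higher, and Potri.009G012600.v3.0 from 0 to 974, at least 210-fold higher. Potri.004G037900.v3.0 went from 442 counts to 0, at least 228-fold lower. Potri.015G135600.v3.0 was 136-fold lower at 96 h (log2 fold change -7.09, SE 0.551), with 21.2 ± 5.05 CPM at 6 h and 0.137 ± 0.121 CPM at 96 h (n = 2 each). Adjusted p by the same test were 1.52e-05, 1.08e-07, 3.37e-08 and 4.18e-08. In OE, 4701 genes were called higher and 5014 lower at 12 h than at 6 h, 5757 and 6106 at 24 h, 7383 and 7164 at 48 h, and 8206 and 7633 at 96 h. The 9715 genes called at 12 h became 6337 without OE 12 h replicate 2.

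The time courses of the genotypes, which share no library, were close to each other. Of the genes called higher in WT, 63%, 70%, 82.6% and 80.1% were also called higher in OE at 12, 24, 48 and 96 h. That was 2916 genes at 12 h and 6385 at 96 h, where independent lists would share 825.1 and 2479. Pearson's r of the log2 fold changes across genes, which are not independent replicates, was 0.608, 0.735, 0.858 and 0.835. Opposite calls were made for 83, 41, 13 and 84 genes. In both genotypes and at each of the 4 later times, some alternatives changed whether more genes were called higher or lower than at 6 h.

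The main question was how OE differed from WT. Averaged over the 5 times, the gene with the largest increase was Potri.014G103000.v3.0 (chromosome 14, 8085842 to 8087890), which was 4.36-fold higher in OE (log2 fold change 2.12, SE 0.114). It stood at 415 ± 109 CPM in OE and 122 ± 15.2 in WT at 6 h, and at 2380 ± 350 and 354 ± 8.76 at 96 h (n = 2 each). All 10 OE libraries lay above both WT libraries of their time. Potri.015G003100.v3.0 (chromosome 15, 236720 to 239777) was 3.84-fold lower (log2 fold change -1.94, SE 0.0929), with 4.16 ± 0.209 CPM in OE and 25.1 ± 4.64 in WT at 24 h. Potri.001G459700.v3.0, which lies in the chromosome 1 segment described further on, was 3.41-fold lower (-1.77, SE 0.0951). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p were 2.76e-08, 1.44e-08 and 2.76e-08.

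Potri.016G141100.v3.0 had a log2 fold change of 2.12 as well (SE 0.468, adjusted p 0.0375 by the same test), at 0.0398 to 5.76 CPM in the WT groups and 1.52 to 6.24 in the OE groups. Its call was lost when any of 13 of the 20 libraries was left out. These were both WT libraries at 6, 12 and 96 h, WT 24 h replicate 1, OE replicate 2 at 6, 48 and 96 h, OE 12 h replicate 1, and both OE libraries at 24 h, with adjusted p from 0.0527 to 0.165.

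In all, 175 genes were called higher and 132 lower in OE on average, 1.16% of those tested. Few of them changed strongly, as 12 were at least 2-fold higher and 27 at least 2-fold lower, and the median size of a called change was 0.488 on the log2 scale. The 307 calls became 202 without WT 6 h replicate 1, 182 without WT 6 h replicate 2, 192 without WT 24 h replicate 2, 181 and 199 without WT 48 h replicates 1 and 2, and 160 without OE 96 h replicate 2. DESeq2 called 501 genes and the additive model 122. Against a log2 fold change of 1, glmTreat called 1 gene higher and 4 lower. More genes were lower than higher with the additive model (65 and 57) and without WT 48 h replicate 1 (96 and 85), OE 48 h replicate 1 (139 and 125) or OE 96 h replicate 1 (149 and 135).

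**Figure D2:**
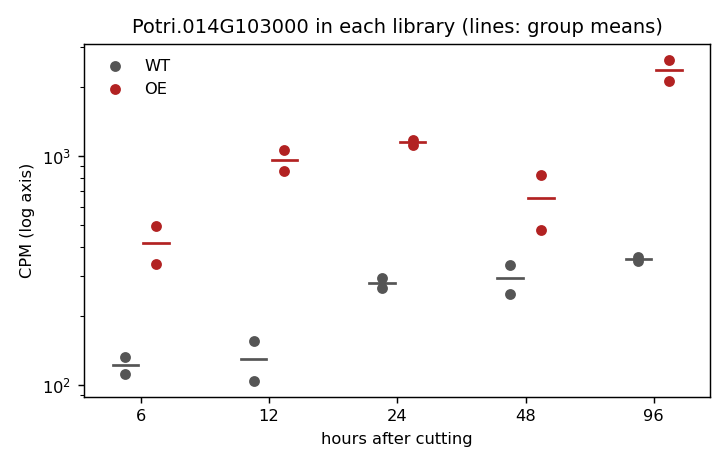
Potri.014G103000.v3.0 in CPM on a log axis against hours after cutting, with 1 point per library (WT grey, OE red) and a line at each group mean. Each OE library lies above both WT libraries of its time, and the lower OE library of a time stands at 1.43 to 5.91 times the higher WT library.

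Part of the difference between the genotypes lay in segments of neighbouring genes, found by the scan that was added after the data had been explored. On chromosome 1, from 49330712 to 49638481, the 14 scanned genes were all lower in OE, with a median log2 difference of -0.893 (quartiles -1.09 and -0.805). The medians by time were -0.712, -1.05, -1.05, -0.928 and -0.889, and the 10 OE libraries ranged from -1.17 to -0.644. On chromosome 13, from 13425 to 2305170, 186 of 189 scanned genes were higher in OE, with a median of 0.202 (quartiles 0.153 and 0.267) and OE libraries from 0.124 to 0.31. The genes next to them had medians of -0.00159 and 0.0199 beside the chromosome 1 segment and 0.0133 beside the chromosome 13 segment, with edges set by the scan itself. The scores were 41.8 and 36.1, against at most 14.5 over 100 shuffles of gene order. Each segment was found again in every scan that left out 1 of the 5 times, although such a scan reuses the other 4. In the time left out, which did not enter the scan, the medians ranged from -1.05 to -0.712 on chromosome 1 and from 0.133 to 0.253 on chromosome 13. The chromosome 1 segment held 14 of the 132 genes called lower on average (10.6%) and the chromosome 13 segment 47 of the 175 called higher (26.9%). With the genes of all segments left out, the test called 195 genes, 98 higher and 97 lower in OE. The excess of higher genes over lower ones (175 and 132) was thus nearly gone.

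**Figure D3:**
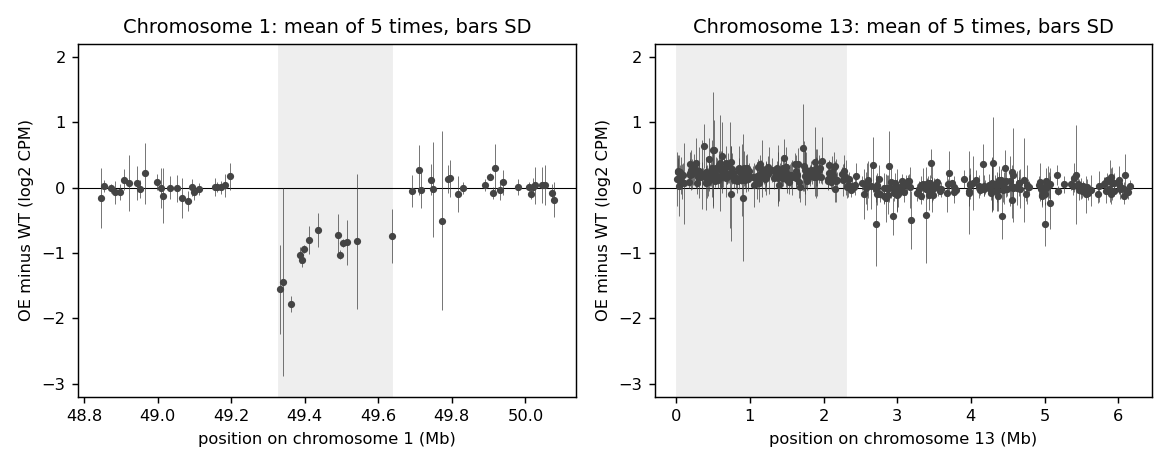
OE minus WT difference in log2 CPM for genes along parts of chromosome 1 (left) and chromosome 13 (right), against position in Mb. Points are means of 5 times, bars the SD over the 5 times, and the grey bands the segments, whose genes have medians of -0.893 and 0.202.

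The comparisons at single times asked at which stage the genotypes differed. At all 5 times, 8 genes were called, each of them lower in OE. Of these, 6 lay on chromosome 1 inside the segment, and the other two were Potri.015G003100.v3.0 and Potri.002G152500.v3.0 (mean log2 fold change -0.95), which was singled out after its values were seen. The 8 became 1 and 0 without WT 48 h replicates 1 and 2, 2 without either OE library at 48 h, 3 without WT 24 h replicate 2 or OE 24 h replicate 2, 5 without any of 7 further libraries, and 0 with the 4 libraries of each time alone. The log2 fold changes between OE and WT at different times, which share no library, had a Pearson's r across genes of -0.079 to 0.25 over the 10 pairs of times. Shared calls were most frequent at 12 and 24 h, with 9 genes higher and 21 lower at both (0.166 and 0.22 for independent lists), and at 24 and 96 h, with 18 and 17 (0.899 and 0.475). In the other 8 pairs, 0 to 4 genes were higher at both times (2 at 6 and 96 h, where independent lists would share 1.2), and 8 to 12 were lower, the 8 genes called at all times among them.

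**Figure D4:**
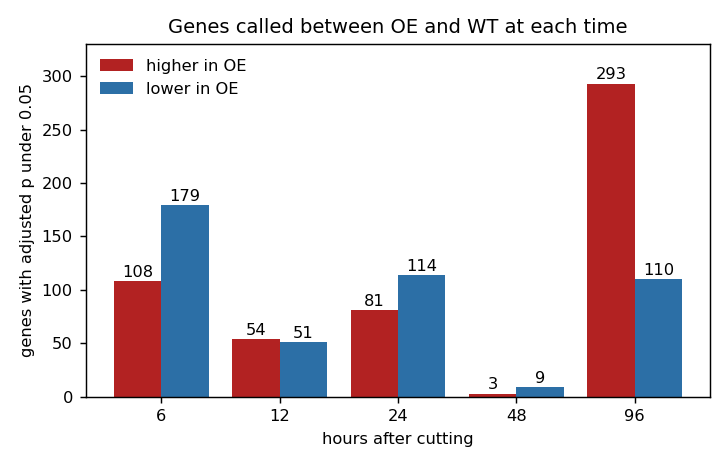
Number of genes with an adjusted p under 0.05 between OE and WT at each time after cutting, with red bars for genes higher in OE and blue bars for genes lower in OE. The counts run from 3 higher and 9 lower at 48 h to 293 higher and 110 lower at 96 h.

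At 6 h, Potri.015G050200.v3.0 was 5.46-fold lower in OE (log2 fold change -2.45, SE 0.299), with 2.94 ± 1.09 CPM against 15.6 ± 3.38 in WT (n = 2 each). Potri.001G051600.v3.0 was 5.15-fold lower (-2.36, SE 0.237), with 18.9 ± 2.66 against 98 ± 15.3 CPM. At 12 h these genes stood at 55.9 ± 9.32 and 202 ± 8.8 CPM in OE and at 32.6 ± 9.58 and 140 ± 32.4 in WT. Potri.007G065400.v3.0 was 3.89-fold higher at 6 h (1.96, SE 0.364), and Potri.013G033300.v3.0, inside the chromosome 13 segment, 3.53-fold higher (1.82, SE 0.305). The adjusted p were 0.00152, 0.000786, 0.0188 and 0.0101 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In total 108 genes were called higher and 179 lower. The 287 calls became 28 without WT 6 h replicate 1, 98 without WT 6 h replicate 2, 137 without OE 6 h replicate 1, 24 with the 4 libraries of that time alone, and 502 with DESeq2. The calls of both higher genes were lost without either WT library (adjusted p 0.0507 to 0.184) and with the 4 libraries alone (0.166 and 0.132), and that of Potri.007G065400.v3.0 also without OE 6 h replicate 1 (0.156).

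At 12 h, Potri.014G103000.v3.0 was 7.43-fold higher in OE (log2 fold change 2.89, SE 0.261), with 962 ± 142 CPM against 129 ± 35.6 (n = 2 each). Potri.016G141100.v3.0 had 179 counts in OE and 2 in WT, a ratio of 103 (95% counting interval 28 to 853). Potri.001G459200.v3.0, inside the chromosome 1 segment, was 10.6-fold lower (-3.41, SE 0.565), and Potri.013G100700.v3.0 4.4-fold lower (-2.14, SE 0.432). The last of these stood at 259 ± 44 CPM in OE and 1140 ± 807 in WT, where the libraries held 39777 and 15576 counts. The adjusted p by the same test were 0.000114, 0.0454, 0.0165 and 0.0454. In total 54 genes were called higher and 51 lower, and neither side was the larger in all alternatives. The 105 calls became 13 without WT 12 h replicate 1, 397 without WT 12 h replicate 2, 37 and 31 without OE 12 h replicates 1 and 2, 175 without either OE library at 6 h, 1 with the 4 libraries of that time alone, and 386 with DESeq2. Without filtering low counts 390 genes were called, and 68 after thinning to the smallest total. The calls of Potri.016G141100.v3.0, Potri.001G459200.v3.0 and Potri.013G100700.v3.0 were lost without WT 12 h replicate 1 (adjusted p 0.375, 0.161 and 0.533), OE 12 h replicate 1 (0.145, 0.0925 and 0.136) or OE 12 h replicate 2 (0.0663, 0.102 and 0.201), and that of Potri.016G141100.v3.0 also without WT 12 h replicate 2 (0.106). With the 4 libraries alone, these calls (0.147, 0.147 and 0.278) and that of Potri.014G103000.v3.0 (0.0695) were lost.

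At 24 h, Potri.015G003100.v3.0 was 6.04-fold lower in OE (log2 fold change -2.59, SE 0.214), and Potri.005G182700.v3.0 7.96-fold lower (-2.99, SE 0.562), with 8 counts in OE and 57 in WT. Potri.002G253400.v3.0 was 7.65-fold higher (2.94, SE 0.421), with 40.8 ± 18.9 CPM in OE and 5.49 ± 4.55 in WT (n = 2 each), and at 12 and 48 h it stood at 6.65 ± 0.494 and 35.8 ± 2.32 CPM in OE and 5.46 ± 0.984 and 35 ± 4.42 in WT. Potri.014G160200.v3.0 was 8.37-fold higher (3.07, SE 0.562), with 149 counts against 16. The adjusted p by the same test were 4.84e-05, 0.0247, 0.00534 and 0.0198. In total 81 genes were called higher and 114 lower, while glmTreat against a log2 fold change of 1 called 2 higher and 1 lower. The 195 calls became 33 and 18 without WT 24 h replicates 1 and 2, 52 and 39 without OE 24 h replicates 1 and 2, and 371 with DESeq2. Without OE 24 h replicate 1, more genes were higher than lower (41 and 11). The call of Potri.005G182700.v3.0 was lost without any of the 4 libraries of that time (adjusted p 0.0643 to 0.192), that of Potri.014G160200.v3.0 without either WT library or OE 24 h replicate 2 (0.138 to 0.147), and that of Potri.002G253400.v3.0 without WT 24 h replicate 2 (0.0647). The same 3 calls were lost with the 4 libraries alone (0.0573, 0.102 and 0.0722).

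At 48 h the fit over all 20 libraries gave the fewest calls, with 3 genes higher and 9 lower in OE, of which 6 lay in the chromosome 1 segment. With the 4 libraries of a time alone, 12 h had fewer (1 against 12). Potri.015G003100.v3.0 was 3.54-fold lower (log2 fold change -1.82, SE 0.213) and Potri.001G459700.v3.0 3.22-fold lower (-1.69, SE 0.215). Potri.008G108100.v3.0 was 2.4-fold higher (1.26, SE 0.2), with 46.8 ± 10.3 CPM against 19.6 ± 1.44 (n = 2 each), and Potri.016G125200.v3.0 2.14-fold higher (1.10, SE 0.185). The adjusted p by the same test were 0.0032, 0.00401, 0.0288 and 0.0473. At an unadjusted p under 0.05 there were 910 genes, and DESeq2 called 40. More genes were higher than lower with DESeq2 (26 and 14), without filtering low counts (18 and 14) and without OE 48 h replicate 2 (3 and 2). The 12 calls became 7 without WT 24 h replicate 2, 2 without WT 48 h replicate 1 or OE 48 h replicate 1, 5 without OE 48 h replicate 2 and 0 without WT 48 h replicate 2, where edgeR gave 848 genes at an unadjusted p under 0.05. Leaving out libraries of that time ended the calls of Potri.015G003100.v3.0 (without WT 48 h replicate 2, adjusted p 0.0639, or OE 48 h replicate 1, 0.0723), Potri.001G459700.v3.0 (without either WT library, 0.072 and 0.0639, or OE 48 h replicate 2, 0.101), Potri.008G108100.v3.0 (without either WT library, 0.32 and 0.764, or OE 48 h replicate 1, 0.414) and Potri.016G125200.v3.0 (without any of the 4, 0.216 to 0.764). The calls of both higher genes were also lost with the 4 libraries alone (0.0617 and 0.123), and that of Potri.016G125200.v3.0 with median-of-ratios size factors (0.0508).

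At 96 h, Potri.005G240200.v3.0 had 1671 counts in OE and 2 in WT, a ratio of 597 (95% counting interval 165 to 4930), although libraries of the same group at other times differed widely, as with 311 and 1 counts in WT at 24 h. Potri.001G099000.v3.0 had 18 counts in OE and 0 in WT, at least 4.29-fold higher. Potri.019G006900.v3.0 was 10.3-fold lower (log2 fold change -3.36, SE 0.309), with 5.97 ± 1.42 CPM in OE and 60.8 ± 20.3 in WT (n = 2 each), and Potri.019G011000.v3.0 9.89-fold lower (-3.31, SE 0.346). These last IDs had nearly equal counts and lengths (1988 and 1919 counts in WT, 789 and 792 bases), so reads may have been shared between copies and their separate values are uncertain. The adjusted p by the same test were 0.0465, 0.0368, 0.00017 and 0.000235. In total 293 genes were called higher and 110 lower, and 142 and 59 of them by at least 2-fold. The excess of higher genes was turned round without WT 96 h replicate 2 (14 higher and 19 lower) and without OE 96 h replicate 2 (9 and 14). The 403 calls became 267 without WT 48 h replicate 1, 33 without WT 96 h replicate 2, 161 and 23 without OE 96 h replicates 1 and 2, 762 with the 4 libraries of that time alone, and 658 without filtering low counts. The calls of Potri.005G240200.v3.0 and Potri.001G099000.v3.0 were lost without any of the 4 libraries of that time (adjusted p 0.0852 to 0.363 and 0.0964 to 0.27).

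A test of whether the OE minus WT difference changed over the time course called 436 genes (1.65%). The smallest adjusted p, 0.00168 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, belonged to Potri.004G114300.v3.0 and Potri.008G027500.v3.0. Potri.004G114300.v3.0 was higher in OE at 6 h and 48 h (log2 fold changes 0.98, SE 0.122, and 1.01, SE 0.119) and stood at -0.48 (SE 0.116) at 12 h, with -0.18 and -0.07 at 24 and 96 h. Potri.008G027500.v3.0 stood at -1.0 (SE 0.328) at 6 h, -1.05 (SE 0.187) at 24 h and 1.73 (SE 0.18) at 96 h, where it reached 11.8 ± 1.01 CPM in OE and 3.57 ± 0.496 in WT (n = 2 each). The count of 436 became 152 and 228 without WT 6 h replicates 1 and 2, 658 without WT 12 h replicate 2, 289 without WT 24 h replicate 2, 245 without either WT library at 48 h, 210 without WT 96 h replicate 2, and 284 and 221 without OE 96 h replicates 1 and 2. DESeq2 called 1306 genes, and 1115 were called without filtering low counts.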

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

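The comparison of positions along the time course was chosen after the results had been seen. The predictions for the direction of the called genes were fixed before their result was seen, but that test was added once the positions had been compared.

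The difference between OE and WT changed over the time course at 436 genes, which is why these were looked at again. Among them were Potri.004G114300.v3.0 and Potri.008G027500.v3.0, each with an adjusted p of 0.00168 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (at most 0.00783 and 0.009 over the 22 alternatives). The first was higher in OE at 6 and 48 h, and the second was lower at 24 h and higher at 96 h. The count of 436 ranged from 152 without WT 6 h replicate 1 to 658 without WT 12 h replicate 2.

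Differences that come and go could arise if the OE cuttings passed through the same time course earlier or later than WT. If that alone were the cause and OE was ahead, nearly all genes called at a time would differ in the direction in which their level was changing. If OE lagged, nearly none would. Outside the segments, 58.5% of 94 genes differed in the direction of change at 12 h (Wilson 95% interval 48.4 to 67.9). At 24 h, 68% of 181 genes did (60.8 to 74.3). Genes are not independent, so the intervals are too narrow. Direction was taken from the change between the time before and the time after. A gene that turns in between can count against a shift that is its only cause. Such turns occurred, as Potri.004G114300.v3.0 stood at 43.2 ± 3.7, 117 ± 5.84 and 62.8 ± 1.94 CPM in WT at 6, 12 and 24 h (n = 2 each). By the limits set beforehand, both shares counted against a shift as the whole cause. Those limits made no allowance for such turns, so the shares cannot decide whether a shift was the whole cause. Higher and lower genes differed at both times. By this measure 43 of 53 and 75 of 80 genes higher in OE were rising over the time course at 12 and 24 h. Of 41 and 101 lower genes, 12 and 48 were falling and 29 and 53 rising. A shift of all or part of the genes stays open. On an axis from the time before (0) to the time after (1), OE minus WT was 0.0396, 0.0386 and 0.00407 at 12, 24 and 48 h. Exact permutation p were 0.89 in either direction and 0.5 in the same direction over 216 arrangements (smallest possible 0.037 and 0.009). An effect of the transgene that differs between times was not tested apart from a shift. Differences between the harvests of single groups, including the hour of day, cannot be told apart from genotype at a time and also stay open.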

How the results depend on the processing

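Leaving out the genes of the segments, thinning to the smallest total and lowering each count by 1 were chosen after seeing the data, and the other settings before. Of 148 counts of called genes recomputed without leaving out a library, 115 stayed within 1.5 times the value reported and 33 did not. DESeq2 called 501 genes in the average of OE against WT, 502, 386, 371 and 40 at 6, 12, 24 and 48 h, and 1306 for the change over time. Without a filter on low counts there were 522 in the average, 390, 377, 32 and 658 at 12, 24, 48 and 96 h, and 1115 for the change over time. The additive model called 122. Against a log2 fold change of 1, which asks for larger changes, edgeR's glmTreat called 5 in the average, 1, 2, 3, 0 and 10 at the 5 times, and for the later times against 6 h 512, 2130, 3287 and 4471 in WT and 420, 1306, 3005 and 3967 in OE. At 48 h, where it called 0, 80 genes had an unadjusted p under 0.05 in glmTreat and 910 in the usual test. Without the genes of the segments the average had 195 and 48 h had 3, where 243 and 6 of the reported calls lay outside them, so the removed genes account for part of the fall only. Thinning to 10399262 counts left 68 at 12 h. The 4 libraries of a time alone gave 24, 1 and 762 at 6, 12 and 96 h. Except where the construction of the setting shows it, the cause was not tested.

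Leaving out each library in turn, 260 of 300 counts stayed within 1.5 times. The ranges that did not were 160 to 427 for the average, 28 to 332, 13 to 397, 18 to 222, 0 to 14 and 23 to 498 at the 5 times in order, 152 to 658 for the change over time, 5841 to 9788 for WT at 12 h against 6 h and 6337 to 9676 for OE. The lowest of these came without OE 96 h replicate 2, WT 6 h replicate 1, WT 12 h replicate 1, WT 24 h replicate 2, WT 48 h replicate 2 (where 848 genes had an unadjusted p under 0.05), OE 96 h replicate 2, WT 6 h replicate 1, WT 12 h replicate 2 and OE 12 h replicate 2. Of 463 alternatives for 58 results on named genes, 392 kept direction and call, 71 kept the direction but lost the call, and none changed sign. Median-of-ratios size factors gave 150 higher and 142 lower in the average, and lowering each count by 1 gave 295 calls, 294 of them shared with the 307. No paired analysis was possible because the labels give no replicate numbers. The gene lists by product with their alternatives, and the alternatives for normalized values alone, were not run, since no IDs were paired with products and counts were at hand. With 2 libraries per group, a difference of 1.5-fold at a single time was recovered for 28.4% of simulated genes at 6 h.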

Other observations

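The tests of the segments, of other splits of the libraries and of the explanations for Potri.014G103000.v3.0 were chosen after the results had been seen. The edgeR comparisons were planned, and only the choice of the genes shown from them in this part came later.

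Potri.013G101000.v3.0, singled out after its values were seen, was among the most abundant transcripts. It took 0.0781 ± 0.012% of the counts in WT at 6 h and 2.55 ± 0.11% at 96 h, and 0.0966 ± 0.0065% and 1.75 ± 0.11% in OE (n = 2 each). Potri.006G085200.v3.0 went from 0.185 ± 0.021% to 1.21 ± 0.061% in WT and from 0.171 ± 0.044% to 1.19 ± 0.071% in OE. Potri.009G012600.v3.0, with at most 1 count in each library up to 48 h, reached 21.1 ± 1.65 CPM in OE and 2.91 ± 0.203 in WT at 96 h (log2 fold change 2.86, SE 0.294, adjusted p 0.00185 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The model Populus_trichocarpa_newGene_213 (chromosome 3, 10291183 to 10292882) had 195 counts over the 10 WT libraries and 3 over the 10 OE libraries, all in 1 of them, a ratio of 72.5 (95% counting interval 24.4 to 354, edgeR adjusted p 0.000531). Potri.014G126200.v3.0 had 185 counts in 3 of the OE libraries and 3 counts in WT (ratio 55.3, interval 18.6 to 271), with an adjusted p of 1 for the average over times. Of the OE counts, 69 and 115 came from the libraries at 96 h, where it stood at 3.9 ± 0.511 CPM in OE and 0.0887 ± 0.0345 in WT (n = 2 each, adjusted p 0.00606 by the same test). These genes were likewise chosen after their values were seen.

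Every OE library lay above both WT libraries of its time at 31 genes and below both at 37, where chance gives 3.39 per direction. When the genotype names were exchanged within times, 1 of 100 splits of the libraries (drawn from 3888) called as many genes as the real one, which was the real one itself with 307 genes, and the highest of the others called 135. A chance division of the libraries within times is thus an unlikely source of the calls averaged over times as a whole. The splits cannot speak to single calls, nor to differences between plant lines or harvests that go with the genotype. A run of 5 genes on chromosome 7 (13567801 to 13604005) passed the scan with a score of 16.6, but its median log2 difference was -1.52 at 24 h and -0.00343 at 48 h, and it was not found with 24 h left out.

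The runs of genes on chromosome 1 and chromosome 13 were weighed first. Their scores of 41.8 and 36.1 exceeded the 14.5 reached by shuffled gene orders, which argues against a chance order of genes that vary independently. Shuffling also breaks up neighbours whose transcripts vary together for other reasons, so it does not test such neighbours as a source. The median over all genes was taken off before scoring, so a shift common to all genes could not affect the scores. The comparison with shuffled orders is therefore no test of the scaling of the libraries. The chromosome 1 median of -0.893, with -1 between the quartiles, is in line with the hypothesis that the OE plants lack 1 of 2 copies of this stretch, although the first 3 genes of the segment lay further down (-1.56, -1.44 and -1.78, SD over the 5 times 0.68, 1.44 and 0.121). The chromosome 13 median of 0.202, from near the chromosome's start, lay well below 0.585. An added copy in every cell would give 0.585 if transcript levels followed copy number. DNA was not measured for either segment. An added copy in all or part of the cells, or another difference between plant lines, thus stay untested candidate explanations. The labels name no number of transgenic lines, so neither the time of such a change nor any tie to the transgene was tested.

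The second pattern was Potri.014G103000.v3.0, which had the largest increase in OE in the average over times, with Potri.016G141100.v3.0 at the same 2.12, but not at each single time. A single library exchanged between the genotypes would place an OE library at or below a WT library of its time. The smallest ratio of an OE library to the higher WT library was 1.43. OE libraries in the chromosome 1 segment were also apart, at -0.644 or lower against at most 0.0708 in size for WT. Potri.014G103000.v3.0 and the segment were both picked for a difference between the genotypes, which limits this check. Libraries exchanged between times within a genotype, or all genotype names reversed, would not show here. All 10 OE libraries lay above both WT libraries of their time, as transcripts of the introduced gene counted at this ID could give. Whether the counts came from the introduced gene, from the plant's own copy or from a gene raised in response cannot be told apart, because no file used here pairs this ID with PuHox52 or separates the transcripts.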
